A study of Mus musculus with 8 samples.

How the data were processed

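RNA from whole lungs of mice was measured on 8 Agilent arrays with 2 colours, 4 from wild-type (WT) mice and 4 from mice carrying an inducible human TGF-β1 transgene (TGFb1-Tg), all on the B6J background and 10 weeks old per the labels. Doxycycline at 1 mg/ml in drinking water switches the transgene on, and the labels give harvests between 2 and 14 days for the study as a whole and no day per sample; the file headers give 14 days for every sample. Per the labels' protocols, total RNA was extracted with Trizol and 100 ng of it was amplified in a pair of RT and IVT rounds. Per the labels, the lung sample was in Cy5 and a pooled control in Cy3 on all 8 arrays, in one dye orientation.

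The sources differ on the pooled control. The labels name a combined wild-type pool for all 8 arrays, and the file headers name a pool of 4 wild-type lungs on water for the WT arrays and a pool of 4 transgenic lungs on water for the TGFb1-Tg arrays. The design fixed beforehand took the labels' single pool as given; the measured pool intensities, given with the results, differ between the array sets. If the headers are right, the difference between the groups is induced transgenic lung over its pool minus wild-type lung over its own pool, and the number of mice behind each pool does not enter its error. Per the headers the WT pool holds the same 4 wild-type lungs as the WT samples, so that the WT mean ratio lies near 0 by construction, and the animals in the transgenic pool contribute no spread. The sources also differ on doxycycline. The labels give the WT samples the same dose as the TGFb1-Tg samples, and the headers put the WT lungs and both pools on water. If the headers are right, doxycycline and transgene induction go together in this design. Which source is right on the WT treatment was not tested.

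The deposited intensity values of both channels had been scaled by the authors to small decimals, and values from 0.01 up are given to 2 decimals. The sample channel was matched to its column through the header and the channel order was checked against the value table. Agilent Feature Extraction 8.5.1.1 is named in the submitters' processing notes; its background correction, dye normalization and error model are not given in the sources used here, nor are the slides, the scan runs or a genome build. The deposited p-value of each probe and array was used only to describe each array. The deposited log10 ratios of the value table matched log10 of the sample over the pool intensity within 0.002 for at least 99.99% of the probes of each array, and lacked 2 probes. The median of the value table was 0 on every array, so its scale, centring and direction are known.

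Of 39341 probes, 6974 were named through a RefSeq accession, 16550 kept a current symbol, 2555 were given an updated symbol and 3984 kept the symbol of the file, using the gene table of GRCm38.p6 for names only. The other 9278 probes had no gene. The 30063 named probes stood for 25734 genes, 22170 with 1 probe and 3564 with several, and a gene's value was the mean of its probes. Between 39039 and 39281 probes were measured per array. Values were missing for 718 probes on some array, and 44.4% of these reached an intensity over 20, against 0.585% of complete probes, so that the brightest transcripts are those least often measured. Scgb1a1, Cyp2f2, Chil3, Sftpc and Col3a1 had too few values for a test. The number of arrays limits the precision, and the median standard error of a gene's difference was 0.0555 on the log2 scale. Every column of per-sample values was used.

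Log2 of the sample over the pool intensity was tested between groups with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with at least 2 values per group and Benjamini-Hochberg adjustment over the 25647 genes tested; 87 genes were not tested. A gene was called at an adjusted p under 0.05. Gene lists were tested with camera of limma at a preset correlation of 0.01 over 45 lists with at least 5 genes complete on all arrays, and again with an estimated correlation and with fry, whose test asks only whether the genes of a list move one way. Tgfb1 was tested with an exact permutation test of 4 against 4 arrays. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. On simulated data for the same comparison with 25303 genes, 68.8% of 80 genes changed by 0.5 on the log2 scale were recovered, 100% of 80 changed by 1 and 97.5% of 40 changed by 2, with 8 false calls and 1 of 1 shifted lists found. The simulation drew independent normal noise for each gene, without rounding, differing pools or correlation within lists. It therefore cannot check the preset correlation of camera.

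The genes called dim have a mean intensity under 0.1. The lists, fixed before the data were examined, covered fibrillar collagens and assembly, non-collagen matrix and elastic fibre, basement membrane, TGF-β direct targets, TGF-β family ligands, contractile myofibroblast, metalloproteinases and inhibitors, alternative macrophage activation, inflammatory cytokines and chemokines, interferon response, complement and acute phase, antigen presentation by MHC class II, cell cycle, p53 and senescence, unfolded protein response, hypoxia and glycolysis, xenobiotic and glutathione metabolism, fatty acid and surfactant lipid metabolism, oxidative phosphorylation, ribosomal proteins, circadian clock, immediate early and heat shock genes, markers of lung and blood cell types and of tissues next to lung, and sex-linked genes, which were not in the camera family. The text names the 10 largest rises and the 10 largest falls among called genes whose 4 TGFb1-Tg values lie outside the range of the 4 WT values, passing over predicted and clone-only symbols, 30 genes fixed beforehand, and from each list the members with the largest rises and falls that passed, at most 4. Some genes that this rule takes are not reported here. The alternatives were another centring, quantile normalization of log ratios, the value table, other rules for probes and dim genes, other eBayes settings, array weights, the replicate number as a block, other thresholds, and each array left out in turn. A filter on mean intensity and a direct comparison of the sample channels were added after the data were seen. The direct comparison used sample intensities quantile normalized between arrays, for probes with a value on every array.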

Results

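Gene expression was compared between lungs of 4 mice with an induced human TGF-β1 transgene (TGFb1-Tg) and lungs of 4 wild-type (WT) littermates, to ask what active TGF-β1, a growth factor that drives fibrosis and tissue remodelling, changes in the lung. Each lung was hybridised in Cy5 against a pooled control in Cy3, and values are differences in mean log2 ratio, TGFb1-Tg minus WT, with the standard error (SE) and 4 mice per group unless stated. The arrays measured between 39039 and 39281 probes each. The standard deviation (SD) of the log2 ratios over probes was 0.13 to 0.16 on the WT arrays and 0.39 to 0.41 on the TGFb1-Tg arrays. Across genes with a mean intensity of at least 0.1, the ratios of the TGFb1-Tg arrays correlated with one another at r of 0.94 to 0.96. Those of the WT arrays did so at -0.26 to 0.19. Arrays of a set share a pool per the headers, so r is not a plain measure of agreement between mice.

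The pooled control was not the same RNA on the 2 sets of arrays. Xist, the non-coding RNA of the inactive X chromosome, had pool intensities of 1.04 to 1.13 on the WT arrays and of 0.01 to 0.02 on the TGFb1-Tg arrays. In the sample channel, WT replicate 1 had a Xist intensity of 4.6 and, on the brighter probe of the Y-linked gene Ddx3y, an intensity of 0.04, as in a female; the other samples had Xist at 0.04 or less and Ddx3y between 6.83 and 10.35. Eif2s3y, Kdm5d and Uty, also Y-linked, were low in WT replicate 1 alone. These values show that the pools differed and do not show whether the second was transgenic or uninduced. If the file headers are right, the group difference sets each TGFb1-Tg lung against a pool of uninduced transgenic lungs and each WT lung against a pool of wild-type lungs.

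**Figure D1:**
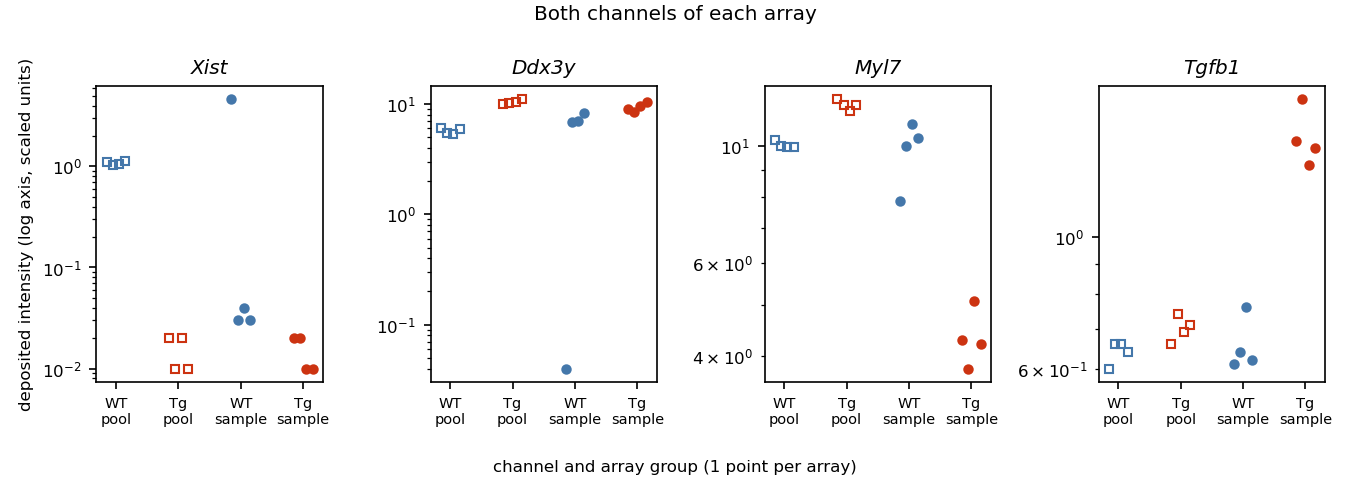
Deposited intensities of Xist, Ddx3y (brighter probe), Myl7 and Tgfb1 on logarithmic axes, 1 point per array, with open squares for the pooled control channel and filled circles for the sample channel, blue for WT and red for TGFb1-Tg arrays. Xist lay at 1.04 to 1.13 in the pool of the WT arrays and at 0.01 to 0.02 in that of the TGFb1-Tg arrays.

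Mouse Tgfb1 was higher in every TGFb1-Tg sample, with a mean log2 ratio of 1.07 ± 0.12 (SD, n = 4) against 0.03 ± 0.12 in WT (SD, n = 4), a difference of 2.04-fold. Over the alternatives the log2 difference ran from 0.63 to 1.09. The exact two-sided permutation test gave p = 0.0286, the smallest this design allows. The probe was designed for the mouse gene and the transgene is human, so that the value checks the transgene only as far as the probe binds its transcript.

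Ratios of sample over pool differed between induced and WT lungs across much of the transcriptome. Of 25647 genes tested, 4874 were higher and 5082 lower, of which 489 and 407 differed at least 2-fold. The pools differed and WT ratios lay near 0, so higher and lower mostly set induced lungs against the pool of their own arrays. The direct comparison of sample channels leaves the pools out. Among the largest rises were Lama1, a laminin chain of basement membranes (3.41 ± 0.16), Ankrd34b (3.34 ± 0.22), Clca1, a secreted product of goblet cells (3.32 ± 0.36), and Ptx3, a pentraxin of innate immunity (3.12 ± 0.12). Tnfsf18, the ligand of GITR, followed at 2.85, then Psca at 2.83, the mitotic genes Pimreg at 2.76 and Pbk at 2.70, the anion exchanger Slc26a4 at 2.71 and Areg, a ligand of the EGF receptor, at 2.70. Among the largest falls were the carboxylesterase Ces1f (-3.21 ± 0.28), the asialoglycoprotein receptor subunit Asgr1 (-3.10 ± 0.12), the glutathione transferases Gsta3 (-2.96 ± 0.16) and Gsta2 (-2.75 ± 0.13), and the tight junction gene Cldn10 (-2.77 ± 0.12). Fgfbp1 changed by -2.64, Rptn by -2.56 and the fast skeletal myosin Myh4 by -2.41. A probe for the pseudogene Cyp4b1-ps2 changed by -2.40 and is uncertain, because the pseudogene resembles Cyp4b1. These largest rises and falls all had limma adjusted p of 0.000395 or less. For Ankrd34b, Clca1, Ptx3, Tnfsf18, Psca, Ces1f, Asgr1, Gsta2 and Rptn the dimmer group mean of a channel was under 0.1, where the 0.01 steps of the intensities are large, so that their sizes and order are approximate; over the alternatives Ankrd34b ran from 2.12 to 4.24 and Clca1 from 2.30 to 3.63. The same limit holds for Il6, Cxcl5, Cenpf, Bmp7, Ncr1 and Ccl24, and for the dim genes. At the other end, Col1a1, Fn1, Eln, Postn, Spp1, Retnla, Cyp4b1, Plvap, Pcolce2, Dcn and Ccl6 reached at least 90% of the highest intensity of a channel on some array; if readings are compressed there, their differences are understated. The 4 TGFb1-Tg values lay outside the WT range for 37.4% of tested genes, where chance gives 2.86%. Quantile normalization of the log ratios, which gives all arrays one spread, left 1603 higher and 1479 lower and brought most differences nearer to 0. It ended the calls of 42 genes named in the text, those of the fixed set being Col1a1, Ccn2, Acta2, Retnla, Cxcl5 and Pecam1. It narrows the ratios of the TGFb1-Tg arrays and widens those of the WT arrays, so a loss of calls follows in part from the method. Here and below, a call that it ended is not by itself a sign of a weak difference. When the sample channels were compared directly, 61.1% of calls were higher, against 49.0% in the ratios, with 5241 higher and 3336 lower.

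Of 45 gene lists, camera called 13 higher and 17 lower at its preset correlation. Some genes belong to more than 1 list, such as Gsta3 to the xenobiotic and the club list, so the lists are not all independent. With an estimated correlation, 0 of 45 lists were called, and the lowest adjusted p was 0.168; fry, which does not compare a list with other genes, called 36. Other divisions of the 8 arrays into 4 and 4 gave up to 25 called lists. Most divisions with 2 arrays of each group on either side also called lists, so camera's adjusted p at the preset correlation may be too small. Counts of members that rose or fell are over all genes tested; adjusted over the list alone, they were the same for 25 lists and moved by at most 3 genes in the other 20.

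Most members of the extracellular matrix lists rose. Of 28 measured genes of the non-collagen matrix and elastic fibre list, 21 rose and 2 fell (median 0.62, camera adjusted p = 4.33e-08; adjusted p = 0.168 with an estimated correlation). Ltbp2, a latent TGF-β binding protein, rose by 2.56 ± 0.14, the glycoprotein Tnc by 2.33 ± 0.09, elastin (Eln) by 1.66 ± 0.13 and fibronectin (Fn1) by 0.81 ± 0.08, while Ltbp1 changed by -0.15 and the hyaluronan synthase Has1 by -0.10. When the sample channels were compared directly, Fn1 was at 0.20 (adjusted p = 0.0942, from 2.51e-05 to 0.0942 over the alternatives), and Ltbp1 and Has1 were not called either. Of 28 fibrillar collagen and assembly genes, 18 rose and 3 fell, or 19 and 3 adjusted over the list alone (median 0.58, camera adjusted p = 1.14e-05; adjusted p = 0.204 with an estimated correlation). Col5a2 rose by 1.76, the procollagen protease Adamts2 by 1.57 and Col1a1 by 0.73, while Pcolce2 changed by -1.46 and decorin (Dcn) by -0.96. Of 19 basement membrane genes, 11 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000987; adjusted p = 0.204 with an estimated correlation), with Lama1 at 3.41 and Col4a6 at -0.42. Of 23 metalloproteinases and inhibitors, 17 rose and 2 fell, or 17 and 3 adjusted over the list alone (median 0.75, camera adjusted p = 1.42e-05; adjusted p = 0.168 with an estimated correlation). Mmp12, the macrophage elastase, rose by 2.60, the cysteine protease Ctsk by 2.53 and the inhibitor Timp1 by 1.58, while Mmp9 changed by -1.44 and Timp4 by -0.52. Postn, a matricellular gene with 2 probes, was at -0.06 (adjusted p = 0.572), and at 0.29 (adjusted p = 0.0337, from 0.0337 to 0.991 over the alternatives) in the direct comparison, where Dcn was at -0.55. Quantile normalization ended the calls of Col1a1, Dcn, Timp4, Ltbp1 and Has1.

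Of 33 direct targets of TGF-β, 19 rose and 9 fell (median 0.22, and 0.31 over the complete genes that camera tested, camera adjusted p = 0.0172; adjusted p = 0.210 with an estimated correlation). The integrin subunit Itgb6 rose by 1.81 and Ccn2 by 0.52, while the co-receptors Tgfbr3 and Eng changed by -1.23 and -1.16. Of 17 ligands and regulators of the TGF-β family, 10 rose and 2 fell (median 0.31, camera adjusted p = 0.00588; adjusted p = 0.168 with an estimated correlation). Fstl1 rose by 1.45 and the activin antagonist Fst by 1.25, while Bmp6 changed by -1.91 and Bmp7 by -0.89. Of 17 contractile myofibroblast genes, 2 rose and 10 fell, or 2 and 11 adjusted over the list alone (median -0.42, camera adjusted p = 0.0118; adjusted p = 0.287 with an estimated correlation). The members that fell included calponin (Cnn1, -1.28), smooth muscle myosin (Myh11, -0.86) and smooth muscle actin (Acta2, -0.42 ± 0.06). Those that rose were Cthrc1 (0.78) and Cdh11 (0.50). Cnn1 is also in the smooth muscle and pericyte list, and RNA of whole lung does not show in which cells these genes fell. In the direct comparison the median of the complete direct targets was 0.49, and Ccn2 was at 0.98 and Myh11 at -1.34. Quantile normalization ended the calls of Ccn2, Bmp7, Acta2 and Cdh11.

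Cell cycle genes and markers of monocytes and recruited macrophages were higher. All 40 measured cell cycle genes rose (median 1.74, camera adjusted p = 3.01e-23; adjusted p = 0.204 with an estimated correlation), with Cenpf at 2.59, Ccna2 at 2.34 and Mki67, a marker of dividing cells, at 2.27 ± 0.14. Of 19 markers of monocytes and recruited macrophages, 17 rose and 0 fell (median 0.73, camera adjusted p = 1.8e-08; adjusted p = 0.177 with an estimated correlation), among them Ms4a6d (1.55) and Cd68 (1.25). Of 21 genes of alternative macrophage activation, 11 rose and 3 fell, or 12 and 4 adjusted over the list alone (median 0.45, camera adjusted p = 0.0118; adjusted p = 0.261 with an estimated correlation). Gpnmb rose by 2.18, Trem2 by 2.09 and Retnla by 1.32 ± 0.23, while Cd163 changed by -0.95 and Ccl24 by -0.86. Arg1 was at 0.45 (adjusted p = 0.101), Spp1 at 0.88 (adjusted p = 0.0800) and Ccl2 at 0.54 (adjusted p = 0.0600); compared directly between sample channels, Spp1 was at 1.79, Ccl2 at 0.99 and Arg1 at 0.62, all called. Over the alternatives, adjusted p ran from 0.00153 to 0.492 for Spp1, from 0.00382 to 0.463 for Ccl2 and from 0.0423 to 0.562 for Arg1. On TGFb1-Tg arrays 2, 3 and 4 the brighter Spp1 probe had sample intensities of 24.35, 23.96 and 23.62, where the highest of any probe were 24.39, 24.17 and 24.06, so that the values of Spp1 may be lower bounds. Without WT replicate 2 Spp1 was called at 1.15, without WT replicate 1 Arg1 at 0.57 and without TGFb1-Tg replicate 3 Ccl2 at 0.69. Of 9 MHC class II genes, 6 rose and 0 fell, or 6 and 2 adjusted over the list alone (median 0.59, camera adjusted p = 0.0186; adjusted p = 0.287 with an estimated correlation), with H2-DMb1 at 0.86 and the transactivator Ciita at 0.80. Of 15 dendritic cell markers, 7 rose and 2 fell (median 0.14, camera adjusted p = 0.0242; adjusted p = 0.416 with an estimated correlation), with Fscn1 at 1.38, Xcr1 at 1.23, Siglech at -0.76 and Zbtb46 at -0.42; Xcr1 was dim. In the direct comparison the dendritic list had a median of 0.50 (adjusted p = 0.00194), and without dim genes it was not called (adjusted p = 0.0810, from 0.00194 to 0.416 over the camera alternatives). Siglech was at -0.43 in the direct comparison. Quantile normalization ended the calls of Retnla, Cd163, Fscn1 and Zbtb46.

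Club cell, ciliated cell and xenobiotic genes were lower, and basal and alveolar type 2 markers higher. Of 29 xenobiotic and glutathione genes, 22 fell and 2 rose (median -1.01, camera adjusted p = 1.88e-08; adjusted p = 0.168 with an estimated correlation); those that rose were Gclc (0.75), which limits glutathione synthesis, and the haem oxygenase Hmox1 (0.52). Of 12 club and secretory cell markers, 10 fell and 2 rose (median -1.03, camera adjusted p = 4.77e-05; adjusted p = 0.168 with an estimated correlation), with Lypd2 at -1.63. Those that rose were Bpifb1 (0.35 ± 0.10), which was at -0.17 (adjusted p = 0.276, from 0.00918 to 0.293 over the alternatives) in the direct comparison, and the dim mucin gene Muc5ac (0.16). Leaving out TGFb1-Tg replicate 3, WT replicate 2 or WT replicate 4 ended the call of Bpifb1, and leaving out any array except TGFb1-Tg replicate 1 or WT replicate 1 that of Muc5ac. Of 13 ciliated cell markers, 12 fell (median -0.74, camera adjusted p = 1.28e-06; adjusted p = 0.206 with an estimated correlation), with Sntn at -0.95, the dynein Dnah9 at -0.94 and Foxj1, the regulator of ciliogenesis, at -0.74 ± 0.07. Of 14 basal and transitional epithelial markers, 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.50, camera adjusted p = 0.0178; adjusted p = 0.168 with an estimated correlation), with Cldn4 at 1.37 and Krt14 at -0.12. Alveolar type 2 markers were higher by camera (adjusted p = 0.0172; adjusted p = 0.210 with an estimated correlation), with 5 risen and 1 fallen of 9 measured, or 6 and 1 adjusted over the list alone. The members that moved most were Fasn (1.36), a lipid synthesis enzyme, the protease Napsa (0.64) and the chitinase Chia1 (-0.98). The type 2 list was not called in the direct comparison (adjusted p = 0.108, from 0.00982 to 0.210 over the camera alternatives), where Hmox1 was at 0.89, Muc5ac at 0.34 and Krt14 at -0.39. Quantile normalization ended the calls of Gclc, Bpifb1, Muc5ac, Sntn, Krt14 and Chia1.

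Lists of endothelial, stromal, muscle and fat genes were called lower. Of 17 alveolar capillary markers, 14 fell (median -0.69, camera adjusted p = 7.78e-08; adjusted p = 0.168 with an estimated correlation), led by the cytochrome P450 gene Cyp4b1 (-2.21 ± 0.10, 4 probes) and the endothelin receptor Ednrb (-2.01), while Car4 was at -0.04 (adjusted p = 0.734). Of 18 general endothelial markers, 14 fell (median -0.58, camera adjusted p = 2.8e-06; adjusted p = 0.177 with an estimated correlation), including Plvap (-1.22) and Pecam1 (-0.48 ± 0.09). Of 22 cardiac and skeletal muscle genes, 20 fell and 1 rose (median -1.35, camera adjusted p = 5.51e-08; adjusted p = 0.168 with an estimated correlation). They included Myh4 (-2.41 ± 0.05) and Nppa (-1.72 ± 0.23), and the member that rose was Tnni2 (0.35). Myh4 is not typical of the skeletal genes, since the mean over 7 of them was -0.57. Over 13 cardiac genes complete on all arrays it was -1.31. Of 15 fat genes, 12 fell (median -0.99, camera adjusted p = 1.31e-05; adjusted p = 0.177 with an estimated correlation), with adiponectin (Adipoq) at -1.76 and Car3 at -1.57. Of 17 fibroblast and lipofibroblast markers, 12 fell and 4 rose (median -0.55, camera adjusted p = 0.0172; adjusted p = 0.272 with an estimated correlation), with Slc7a10 at -2.32, Wnt2 at -1.42, Mfap4 at 0.65 and the lipid droplet gene Plin2 at 0.55. Of 18 smooth muscle and pericyte markers, 10 fell and 2 rose, or 11 and 4 adjusted over the list alone (median -0.20, camera adjusted p = 0.0172, or 0.365 with an estimated correlation). Those that rose were Rgs5 at 0.43 and Kcnj8 at 0.29, and Rgs5 was not called in the direct comparison (0.02). The largest fall was that of Cnn1 (-1.28), which also led the contractile myofibroblast list, so that the 2 lists are not independent. Of 12 mesothelial markers, 6 fell and 1 rose (median -0.33, and -0.59 over the 11 complete genes that camera tested, camera adjusted p = 0.0201; adjusted p = 0.439 with an estimated correlation), with Wt1 at -1.18, Rspo1 at -1.08 and Krt19, with 3 TGFb1-Tg values, at 0.56. The mesothelial list was not called without TGFb1-Tg replicate 2 (adjusted p = 0.0831, from 0.00711 to 0.439 over the camera alternatives), and the mesothelial, fibroblast and smooth muscle lists were not called after quantile normalization, which also ended the calls of Pecam1, Tnni2, Adipoq, Wnt2, Kcnj8, Krt19 and Wt1. Wt1 was at -0.65 in the direct comparison. Kcnj8 also lost its call without TGFb1-Tg replicate 2 or WT replicate 2, 3 or 4.

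**Figure D2:**
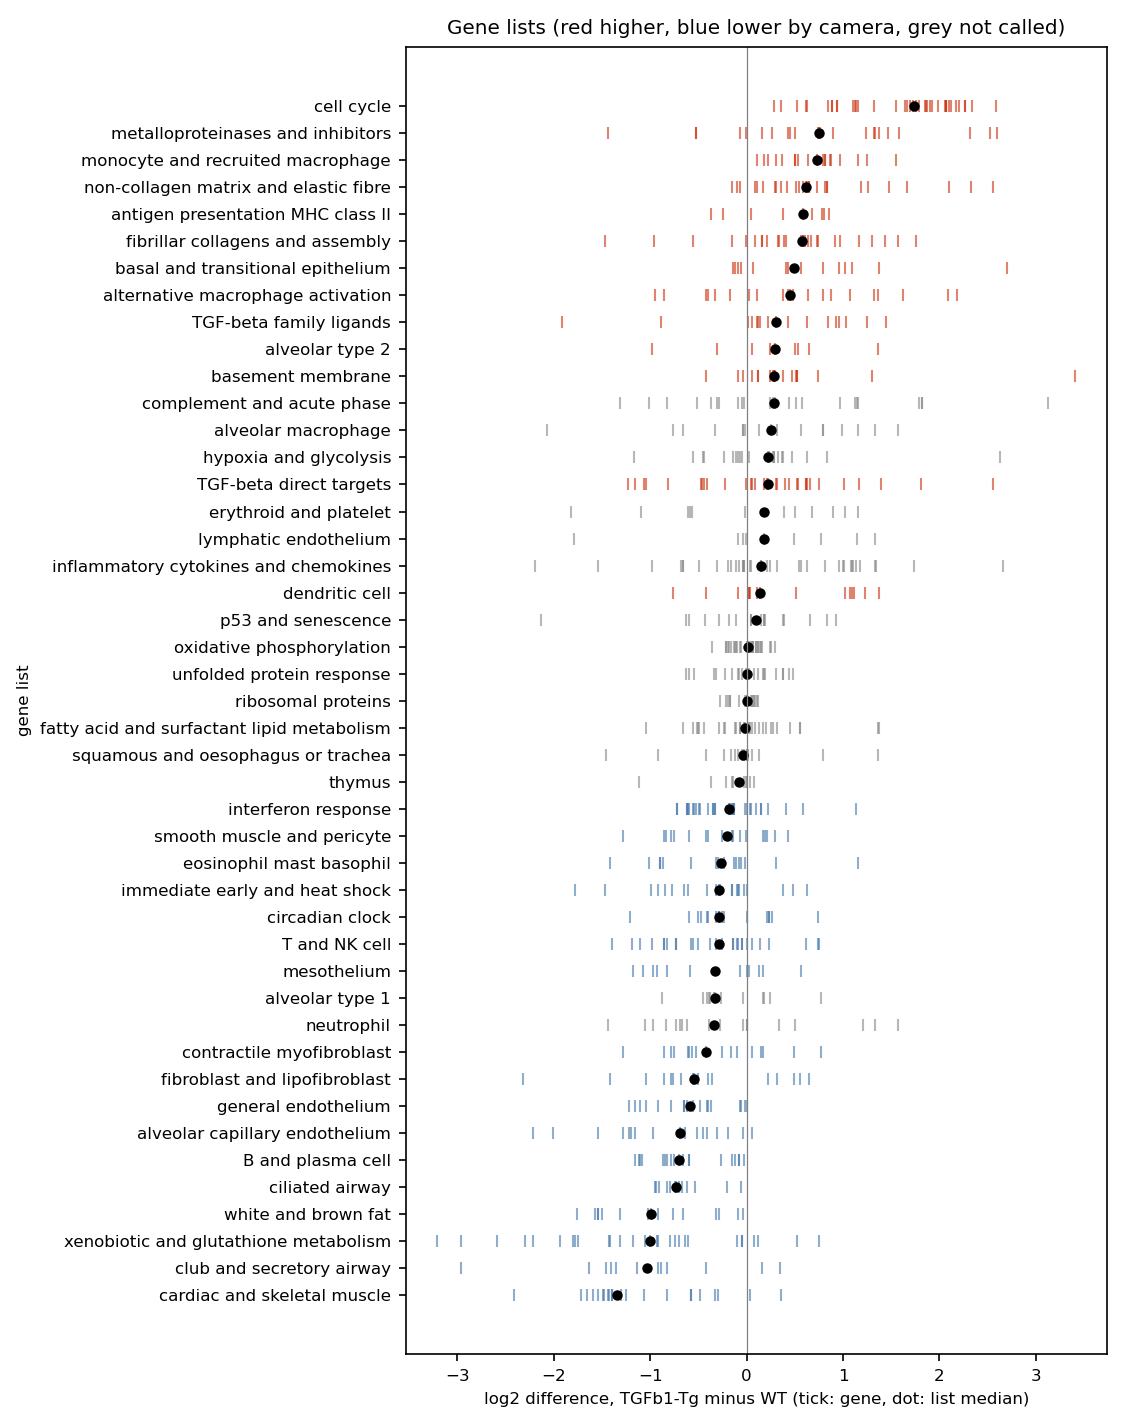
Log2 differences between TGFb1-Tg and WT arrays (x axis) for the 45 gene lists (y axis), with 1 tick per gene and a black dot at the list's median; lists called higher by camera at the preset correlation are red, those called lower blue and the others grey. The cell cycle list lies highest, with a median of 1.74, and the cardiac and skeletal muscle list lowest, with a median of -1.35.

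The lists of B and plasma cells, of T and NK cells, and of eosinophils, mast cells and basophils were called lower. Of 19 B and plasma cell markers, 11 fell, or 14 adjusted over the list alone (median -0.70, camera adjusted p = 0.000185; adjusted p = 0.360 with an estimated correlation), among them Ms4a1 (-1.12 ± 0.28) and Fcrla (-1.10). Of 28 T and NK cell markers, 13 fell and 3 rose, or 15 and 3 adjusted over the list alone (median -0.29, camera adjusted p = 0.00835; adjusted p = 0.439 with an estimated correlation). The granzyme Gzma (-1.40) and the NK receptor Ncr1 (-1.19) fell, and Cd2 (0.76) and Ctla4 (0.74) rose. Of 16 eosinophil, mast cell and basophil markers, 7 fell and 2 rose, or 10 and 2 adjusted over the list alone (median -0.26, camera adjusted p = 0.0118; adjusted p = 0.168 with an estimated correlation), with Gata2 at -1.41, Fcer1a at -1.01, Siglec5 at 1.15 and Il1rl1 at 0.31. The direct comparison did not call these lists, nor Ms4a1 (-0.45), Ncr1 (-0.32) and Fcer1a (-0.51), and gave -0.54 for Fcrla, -0.90 for Gzma, 1.17 for the dim gene Ctla4 and 0.48 for Il1rl1. Fcer1a was dim, and its call ended in each alternative that left out an array except TGFb1-Tg replicate 1; without dim genes the eosinophil, mast cell and basophil list was not called. Quantile normalization ended the calls of Ms4a1, Fcrla, Cd2, Il1rl1 and Fcer1a.

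Of 33 interferon response genes, 13 fell and 4 rose, or 16 and 4 adjusted over the list alone (median -0.18, camera adjusted p = 0.0242; adjusted p = 0.499 with an estimated correlation), with Ifi44 and Gbp2 both at -0.72, Cxcl10 at 1.13 and Oas2 at 0.58. Of 22 immediate early and heat shock genes, 10 fell and 3 rose (median -0.28, camera adjusted p = 0.0219; adjusted p = 0.383 with an estimated correlation), with Hspa1b at -1.78, Hspa1a at -1.46, Junb at 0.62 and Atf3 at 0.48. Of 18 circadian clock genes, 10 fell and 2 rose, or 11 and 2 adjusted over the list alone (median -0.28, camera adjusted p = 0.0311; adjusted p = 0.210 with an estimated correlation), with Hlf at -1.21, Nr1d1 at -0.60, Wee1 at 0.74 and Bhlhe41 at 0.26. Neither the direct comparison nor quantile normalization gave a call for these lists, and quantile normalization ended the calls of all members named except Wee1 and Hlf. The immediate early and heat shock list was not called without WT replicate 1 either (adjusted p = 0.0652, from 0.00895 to 0.383 over the camera alternatives), and Atf3 lost its call when any of TGFb1-Tg replicates 2, 3 and 4 or WT replicates 2, 3 and 4 was left out. The circadian list was not called without dim genes either. In the direct comparison Hlf was at -0.68 and Bhlhe41 at 0.42. Bhlhe41 lost its call without TGFb1-Tg replicate 2 or WT replicate 4.

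The other 15 lists were not called by camera. Of their members, 7 rose and 3 fell of 17 alveolar macrophage markers, 13 and 6 of 24 complement and acute phase genes, 4 and 1 of 9 lymphatic markers, 15 and 8 of 39 cytokines and chemokines, 12 and 5 of 23 hypoxia and glycolysis genes, 0 and 2 of 10 thymus markers, and 1 and 4 of 13 alveolar type 1 markers. Of 22 genes of the unfolded protein response 9 rose and 6 fell, of 16 squamous and oesophageal genes 2 and 3, of 18 p53 and senescence genes 7 and 5, of 18 neutrophil markers 5 and 6, and of 12 erythroid and platelet genes 1 and 5. Of 16 ribosomal protein genes 1 rose and 2 fell, of 31 fatty acid and surfactant lipid genes 10 and 10, and of 33 oxidative phosphorylation genes 6 and 6. Their adjusted p was 0.0758 for alveolar macrophages, 0.0907 for complement and acute phase, 0.0972 for lymphatic endothelium, 0.121 for cytokines and chemokines, 0.155 for hypoxia and glycolysis and 0.350 for thymus. It was 0.382 for alveolar type 1 cells, 0.454 for the unfolded protein response, 0.461 for squamous and oesophageal genes, 0.545 for p53 and senescence, 0.565 for neutrophils, 0.684 for erythroid cells and platelets, 0.756 for ribosomal proteins, 0.759 for fatty acid and surfactant lipid metabolism and 0.774 for oxidative phosphorylation. Single members passed the gene test, such as Il6 (2.66) and Ccl6 (1.74) upward and Cxcl5 (-2.19 ± 0.29) downward among cytokines, Saa3 (1.82) among acute phase genes and Cdkn1a (0.66 ± 0.07), a cell cycle inhibitor, outside them; the sizes for Il6 and Cxcl5 are approximate, with a group mean under 0.1 in a channel. Cxcl5 was at -0.84 in the direct comparison and was not called after quantile normalization. In the direct comparison the cytokine list was called higher (adjusted p = 0.00192, from 0.00192 to 0.632 over the camera alternatives) and the squamous list lower (adjusted p = 0.0446, from 0.0446 to 0.689). The alveolar macrophage list was called higher without TGFb1-Tg replicate 1 or 3 and after quantile normalization, the complement list after quantile normalization or with the brightest probe per gene, and the cytokine list without TGFb1-Tg replicate 3. Il13ra2 was dim, at 0.15 (adjusted p = 0.449). Median, mean and camera direction differed in sign for the p53, ribosomal, fatty acid and erythroid lists.

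**Figure D3:**
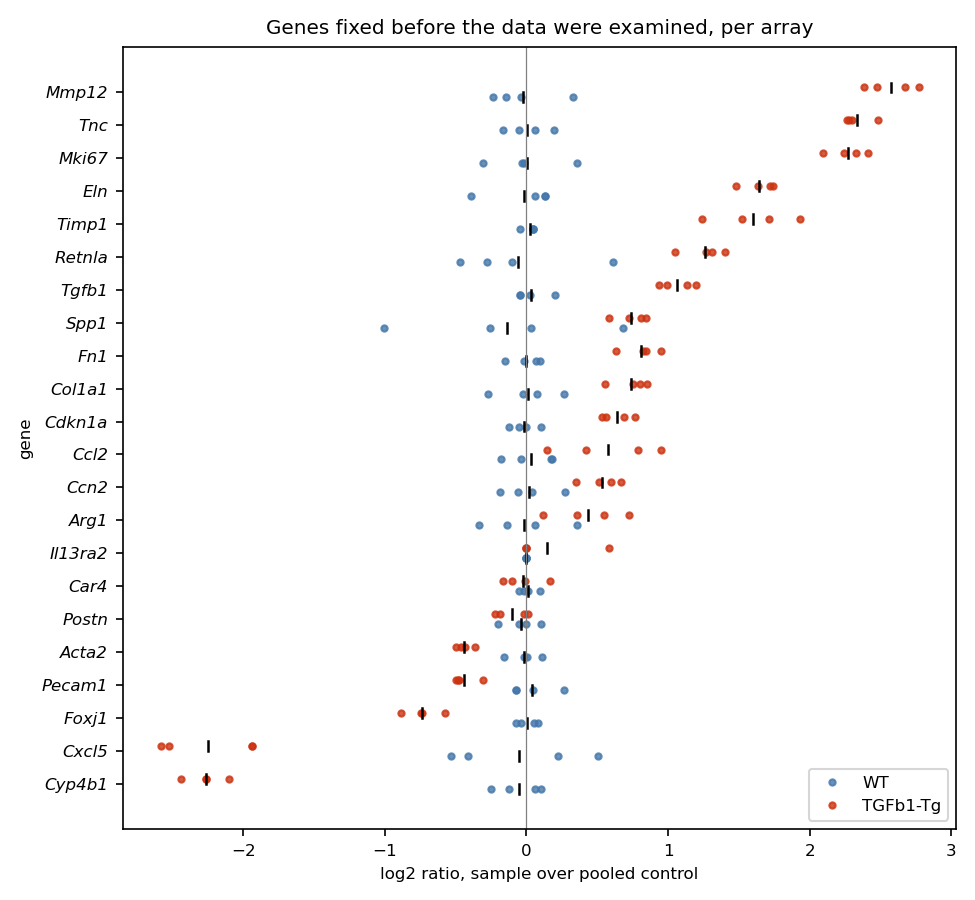
Log2 ratios of the sample over the pooled control (x axis) for genes of the fixed set (y axis), with 1 point per array, blue for WT and red for TGFb1-Tg, and a black bar at each group's mean. Mmp12, Tnc and Mki67 lie highest in TGFb1-Tg lungs and Cyp4b1 lowest, and the groups overlap for Spp1, Ccl2, Arg1, Il13ra2, Car4 and Postn.

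Transcripts bright enough to leave values missing could be read only on some arrays. On TGFb1-Tg arrays 1, 3 and 4, the club cell secretoglobin Scgb1a1 had pool intensities of 25.03, 26.57 and 27.83 and sample intensities of 8.22, 6.27 and 9.46. Cyp2f2, a club cell cytochrome, had pool intensities of 23.72, 24.35 and 27.94 and sample intensities of 6.68, 6.18 and 11.09 on the same arrays. Neither had a value on a WT array.

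The WT arrays were also set against their own pool. Per the headers it held the same 4 lungs, so that mean ratios lie near 0 by construction and the count gives no background rate. With limma, 0 of 25708 genes passed an adjusted p under 0.05, and 378 had an unadjusted p under 0.05. Both channels of all arrays were also quantile normalized together, for 11406 genes with intensity of at least 0.3. Log2 of the mean WT sample over the mean WT pool then had an SD over genes of 0.0278, against 0.438 on the TGFb1-Tg arrays. The WT value goes with a pool of the same lungs, as the headers give it. The spread between mice, as the median SD of a gene's log2 ratio, was 0.0700 among TGFb1-Tg lungs and 0.0706 among WT lungs (n = 4 each).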

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

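The check for single arrays far from the other 3 of their group followed a rule set in advance, and no test in this part was chosen after the result was seen. It covered 323 sets of 4 values of named genes, sex-linked genes and called lists; 27 sets (8.36%) held an array whose gap to the nearest other exceeded Dixon's 95% critical value, where chance gives about 1 in 20. Values are log2 ratios of sample over pool, and for a list their mean over its genes.

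WT replicate 1 stood apart for Xist (2.06, other WT arrays -5.24 to -4.71) and for the Y-linked genes Ddx3y (-6.21, others 0.29 to 0.39), Kdm5d (-4.91), Eif2s3y (-3.92) and Uty (-3.32), as well as for Ces1f (-0.60) and Junb (0.16). The labels give no sex for any animal, and no biological explanation was tested beyond these values.

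Among the other WT arrays, replicate 2 stood apart for Eln (-0.39, others 0.06 to 0.13), Timp1 (-0.046), Psca (0.22) and Ankrd34b (0.58), replicate 3 for Gpnmb (0.19), Krt14 (-0.035), Fcer1a (0.58) and the alveolar capillary list (0.063), and replicate 4 for Hspa1a (0.50). For Psca, Krt14, Ankrd34b and Fcer1a the other 3 WT arrays were all at 0, and 1 step of 0.01 between the channels set the remaining array apart.

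TGFb1-Tg replicate 3 stood apart for Areg (2.35, others 2.74 to 2.82), Tnc (2.48), Pecam1 (-0.31), Pcolce2 (-1.19), Ms4a1 (-1.61), Il13ra2 (0.58, others all at 0) and the basal and transitional epithelial list (0.51). TGFb1-Tg replicate 2 stood apart for Hmox1 (0.56), the monocyte and recruited macrophage list (0.80, others 0.65 to 0.67), the club and secretory list (-0.94, others -1.10 to -1.07) and the dendritic cell list (0.55). TGFb1-Tg replicates 1 and 4 stood apart in 0 sets.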

How the results depend on the processing

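The filter on mean intensity and the direct comparison of sample channels were added after the data were seen; the other alternatives were planned. Quantile normalization of the log ratios called 1603 genes higher and 1479 lower, of which 3073 were among the 9956 called without it. It called 15 lists higher and 11 lower. It gives every array one spread, although the TGFb1-Tg arrays spread more, so that fewer gene calls follow in part by construction. At least 2-fold differences left 489 and 407 genes, fewer by construction. With an estimated correlation, 0 lists were called higher and 0 lower. The direct comparison called 5241 genes higher and 3336 lower, with 5703 shared, and 13 and 12 lists; Bpifb1 went from 0.35 to -0.17. The pools drop out there, but the sample intensities were also quantile normalized, so the change cannot be credited to the pools alone. The cause was not tested further. Across genes, which are not independent replicates, the direct and ratio differences correlated at r = 0.765; 857 of 890 calls of at least 2-fold were called in the same direction, and 120 genes were called in opposite directions.

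Leaving out each array in turn gave 4277 to 4570 genes higher and 4497 to 4821 lower, 13 to 15 lists higher and 16 to 17 lower, and Tgfb1 differences of 0.99 to 1.09. The replicate block gave 4359 genes higher and 4492 lower, with 13 and 17 lists; arrays with the same number deviated together at r of -0.035 to 0.050, so that the numbers do not pair the lungs. Over all settings, values of named genes and lists kept their direction and side of the threshold in 2460 and 786 cases, lost it in 88 and 48, gained it in 13 and 14, moved where the ratios gave no call in 7 and 6, Postn in the direct comparison among them, and reversed in 1 and 0. Median centring moved nothing, because every array was already centred. Normexp with loess and a slide or scan block were not run. Of 8775 dim genes, with intensity under 0.1, 12.7% were called, against 52.4% of 16872 brighter genes; low signal, rounding and absent expression were not separated.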

Other observations

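The scan of gene families, the pool tests, the test of cardiac genes and the bound on rounding were chosen after the results were seen. Families were formed by symbol, with 257 of at least 8 genes, and their calls were set against those of 16872 genes with intensity of at least 0.1, of which 25.5% were higher and 26.9% lower (one-sided Fisher's exact test, adjusted over 514 tests). Lower calls were enriched among Cfap genes of the ciliary axoneme (21 of 25, adjusted p = 2.10e-06), Klra genes, which encode Ly49 receptors of NK cells (16 of 18, adjusted p = 1.66e-05, median -1.23, and -0.61 when sample channels were compared directly), Pcdha protocadherins (10 of 10, adjusted p = 0.000342), Cyp genes (28 of 53, adjusted p = 0.00717), Gimap GTPases of lymphocytes (7 of 8, adjusted p = 0.0358) and Tbx transcription factors (8 of 10, adjusted p = 0.0370). Members of the Pcdha and Klra families share sequence, so that their probes do not count as separate genes. For all families, Fisher's test takes genes as independent, although members can move together on the same 8 arrays. No allowance for correlation was made, so the adjusted p of families may be too small. With an estimated correlation, 0 of 45 lists were called.

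Higher calls were enriched among Col collagen genes (18 of 32, adjusted p = 0.0209), Atp genes (30 of 66, adjusted p = 0.0248), Tnfrsf receptors (11 of 16, adjusted p = 0.0248), Man genes (7 of 8, adjusted p = 0.0276), Mmp genes (9 of 13, adjusted p = 0.0487) and Slc transporters (89 of 261, adjusted p = 0.0487). The family medians kept their sign after quantile normalization of the log ratios and in the direct comparison of sample channels, except that of Slc (0.01), which was at -0.0058 after quantile normalization. Calls within families were not set against the background again under those scalings.

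For the genes, 1 of 35 divisions into 4 and 4 called as many as the real one, the smallest share this design allows. The real division called 9956 genes and the others 2 at most. This argues against a chance division of the arrays, but not against another difference between the array sets, such as their pools or a batch. For the lists the share was also 1 of 35, with 30 lists against 25 at most elsewhere, in divisions that exchanged 1 array of each group. Divisions with 2 of each group on either side set no group against the other and gave 8 at most. Most of them called at least 1 list, so the adjusted p of camera at its preset correlation may be too small. Rounding of intensities to 2 decimals is argued against as the source of most differences, since 85.0% of the called genes differed by more than rounding of all their intensities by 0.005 could give. For the dim genes, of which 12.7% were called, its part stays open, because low signal also lowers the share of calls.

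Markers of several resident lung cell types were lower. Dilution of resident RNA by other cells would move them alike, but 15 of 15 pairs of 6 lists lay over 2 standard errors apart over the TGFb1-Tg arrays, and 8 over genes. Those 8 all set the alveolar type 2 list (mean 0.26) or the type 1 list (-0.16) against the lists that fell, whose means were -1.04 for club cells, -0.67 for ciliated cells, -0.58 for endothelium and -0.87 for capillaries. The error over arrays took the WT means as fixed, although the type 1 list mean spread more in WT (SD 0.225) than in TGFb1-Tg lungs (0.0889). The type 2 list rests on 9 of its 15 listed genes. The 8 pairs argue against dilution as the whole cause. A part of the fall may still come from it, since the lists that fell were not separated from one another over genes. An effect of TGF-β1 on these cells stays open and was not tested.

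Cardiac and skeletal muscle genes were lower, and 0 of them are in another list. Muscle carried over into the pool of the TGFb1-Tg arrays is argued against by the pool differences. As a share of the size of the fall, these were -0.00573 ± 0.0997 (SE) for 7 skeletal genes. For 13 cardiac genes complete on all arrays the share was 0.0247 ± 0.0443 (SE). The skeletal fall (mean -0.57) was uneven, with Myh4 at -2.41 and Tnni2 at 0.35. The 13 cardiac genes with intensity of at least 1 were all lower, from -1.72 to -0.58, with an SD of 0.281 around a mean of -1.41. The median SD in 35 other lists was 0.634, and 4 of them had a smaller one. Many of those lists hold genes that rose and genes that fell, which widens their SD. Myl7, an abundant atrial gene, had sample intensities of 3.79 to 5.09 in TGFb1-Tg and 7.88 to 11 in WT lungs. A smaller share of cardiac-type muscle in the TGFb1-Tg samples, from dissection or from the lung veins, is a candidate explanation, and shared regulation of these genes would give the same SD.

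The pooled control differed between the array sets. One pool on all arrays is excluded by Xist, with deposited pool intensities of 1.04 to 1.13 on the WT arrays and of 0.02 at most, near the finest step, on the TGFb1-Tg arrays. Pool differences here and for the muscle genes are log2 values after quantile normalization of both channels of all arrays together. The Xist difference of -5.88 on that scale stands only for a large one. Genes at least 2-fold higher in TGFb1-Tg lungs had a median pool difference above that of genes at least 2-fold lower by 0.0921 (bootstrap interval 0.0445 to 0.145), but each pool is 1 RNA and the interval, taken over genes, holds no spread between pools, so transgene activity without doxycycline stays open. A hybridisation or scan batch, which acts on many probes, is argued against for Xist, at 26.8 SD of the pool differences over genes; for the other pool differences, with 0 fields of batch, slide or scan in the labels and headers, batch and group cannot be told apart. Among 11406 genes with intensity of at least 0.3, 29 differed at least 2-fold between the pools with no overlap of arrays. Of these, 10 were higher and 19 lower on the TGFb1-Tg arrays. Spp1 (0.80), Ccn1 (1.39), Egr1 (1.02), Jchain (1.14) and Cyp1a1 (-1.12), which differed between the pools, were picked after their values were seen. They do not reflect these counts.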
